A study of Oryza sativa with 12 samples.

How the data were processed

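The deposited series matrix held intensity values on a linear scale, produced with MAS5 per the submitters' processing notes, with values from 0.1 to 57846. Arrays had been scaled by the authors: the 2% trimmed means lay between 500.06 and 500.08. Per the labels, RNA was extracted with RNeasy columns and labelled with the Affymetrix one-cycle kit. Scanner, software version, detection calls and the date of each hybridisation were not given in the sources used here, nor were growth conditions and the direction of the cross.

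Of 57381 probe sets, 123 control sets were left out. Arrays were rescaled to a trimmed mean of 500 and log2(signal + 16) was taken. A probe set was kept when its group mean exceeded a threshold in at least 1 of 6 groups, which left 42974 (75.05%). The threshold was the mean of the 40th percentiles of the 12 arrays (5.59, a signal of 32.2). A linear model with 6 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend (6 residual and 4.581 prior degrees of freedom). P-values were adjusted by Benjamini and Hochberg at 0.05 within each comparison. The comparisons were F1 against the mean of both parental log2 values in each tissue, F1 beyond both parents, C bao against Jamaica in each tissue, and the leaf minus root difference of the F1 effect. For beyond both parents the larger of 2 p-values was taken where both differences had 1 sign. Tables and figures were made with Python 3.11.15.

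Probe sets were named from the probe annotation and a table of gene symbols. There were 22436 probe sets with 1 gene, 95 with several and 34727 with none in that table, and the 17905 genes were all found in the reference, 2457 of them with an informative name. Signals are means ± SD of 2 arrays, and a change carries the limma standard error. Adjusted p-values of single genes are from limma.

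Gene lists were fixed as 28 themes of defence, stress, hormones, nutrients, growth and other tissues, of which 22 had at least 5 genes and were tested with camera on the probe set of highest mean per gene (inter-gene correlation 0.01). An estimated correlation and fry were the alternatives. With an estimated correlation 0 lists passed in leaf and 0 in root, against 4 and 6 with camera as set and 0 and 9 with fry. "Adjusted over the list alone" means Benjamini and Hochberg within the list. Symbol patterns for list members were written after the annotation tables were seen, since these gave symbols rather than descriptions, but before any result per gene.

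Named genes followed a fixed rule: the 6 largest rises and falls beyond both parents with both F1 arrays outside all 4 parental arrays, up to 3 per list, 16 defence markers (7 not found by name), 3 each way per tissue for the parents among genes called in both tissues, and 4 each way for the leaf minus root difference. Only genes with an informative name were eligible, and in leaf the first part named no gene. Genes outside the rule are described as chosen after their values were seen. The comparisons, filter, lists, naming rule and most alternatives were chosen before the data were examined. The actin, Gapdh, cyclophilin and ubiquitin control sets for the 3' to 5' comparison were changed to rice ones afterwards.

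In a self-test the scripts were run on simulated arrays in which 200 probe sets were changed in F1 roots. A log2 change of 1 was recovered in 9% of cases (0% beyond both parents) and a change of 2 in 52% (33%). Mean estimates of the rises were 1.003 and 1.972, 4 of 65 calls were false, and the unchanged leaf comparison gave 0 calls. In the simulation a change of 1 was therefore mostly missed. Only 200 of 42974 probe sets were changed in it, whereas the real F1 roots gave 2174 calls. The adjusted threshold is stricter with fewer changed probe sets, so these shares need not hold for the real arrays. Simulated errors were independent between probe sets, with the same SD for a probe set in all 6 groups. The real F1 leaf pair spread more than any other pair. The 0 leaf calls therefore do not measure false calls in the real leaf comparison.

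The alternatives were quantile scaling, median centring, a pseudocount of 1 or 64, no filter or one at the 60th percentile, a linear mid-parent value, each tissue fitted alone, moderation without trend or robust, array weights, a replicate block, a threshold of 0.01, a further threshold of 2-fold, lists over all probe sets of each gene and leaving out each array. Leaving out both F1 leaf arrays for root results and a covariate of the dividing-cell mean for leaf results were added after the data had been seen. Probe-level data were not used here, and splicing, alleles and genome positions were not analysed here.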

Results

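Gene expression was compared on 12 Affymetrix rice arrays covering the cultivars C bao and Jamaica and the F1 hybrid from their cross. Hybrid weakness is poor growth of a hybrid whose parents grow normally, and the series title links it to the stress response. Leaves were 4 weeks old and roots 7 days old, so tissue and age could not be told apart. Each of the 6 groups of genotype and tissue held 2 arrays. The labels do not say that replicates came from separate plants, so every p-value measures only the spread between these samples. The number of arrays limits the precision of every estimate. Of 57258 rice probe sets, 42974 (75.05%) passed the signal filter, and changes are log2 differences from limma with its standard error (SE).

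The pair of F1 leaf arrays resembled each other less than any other pair of replicates (r = 0.92, with 9717 probe sets more than 2-fold apart). The other pairs reached r = 0.94 for Jamaica leaf and 0.97 for C bao leaf and for each root group. The SD of the replicate difference across probe sets, over the square root of 2, was 0.691 for F1 leaf and 0.5965 for Jamaica leaf. It was 0.459 for C bao leaf and 0.4299 to 0.4535 for the root groups. Since limma used 1 spread estimate per probe set for all 6 groups, leaf standard errors may be too small and root ones too large. The mean log2 signal of 33 genes of dividing cells was 9.86 on F1 leaf replicate 1 and 7.72 on replicate 2. C bao leaves gave 9.60 and 9.78 and Jamaica leaves 7.67 and 8.09. Genes induced by abscisic acid and drying went the other way, with a mean of 7.79 on F1 leaf replicate 1 and 11.09 on replicate 2. In F1 roots the same 9 genes stood at 13.48 and 13.54, and on all remaining arrays between 7.08 and 8.02. The 3' actin control gave signals of 9769 and 1368 on F1 leaf replicates 1 and 2, against 9516 and 9367 in C bao and 2440 and 2301 in Jamaica leaves.

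**Figure D1:**
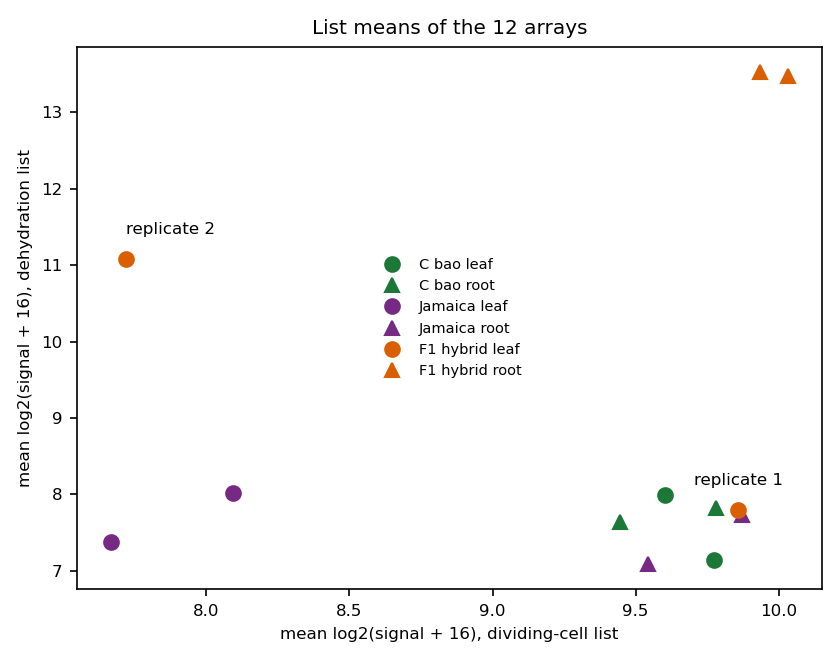
Mean log2(signal + 16) of 33 dividing-cell genes (x axis) against that of 9 genes induced by abscisic acid and drying (y axis), with 1 point per array, circles for leaf and triangles for root, coloured by genotype. The F1 root arrays stood highest for the drying-induced genes (13.48 and 13.54), and the 2 F1 leaf arrays lay apart on both axes (9.86 and 7.72 for dividing cells).

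Among genes with an informative name, the 3 largest rises in F1 roots beyond both parents were in genes for dehydrins, which accumulate in maturing seeds and drying tissue. RAB21 had a signal of 36329 ± 8487 in F1 roots, 135 ± 2.54 in C bao and 118 ± 158 in Jamaica (mean ± SD, n = 2 each), a change of 8.42 against the mid-parent value (SE 1.30, adjusted p = 0.0038). RAB16C rose by 8.39 (SE 0.844, adjusted p = 0.000322), from 24.9 ± 28.5 and 43.9 ± 12.6 in C bao and Jamaica to 15409 ± 388 (n = 2 each). RAB16B rose by 7.95 (SE 1.12, adjusted p = 0.00227). These 3 genes have neighbouring gene identifiers and similar names, so signal shared between their probe sets was not excluded and they are not 3 independent results. After these dehydrin genes came PM1, which rose by 6.73 (SE 0.400, adjusted p = 3.02e-05), from 117 ± 30.0 and 221 ± 60.8 to 18539 ± 946 (n = 2 each).

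Of the 9 genes of the abscisic acid and dehydration list, 7 rose in F1 roots against the mid-parent value, 0 fell and 2 did not pass. Adjusted over the list alone 8 rose and 0 fell. The list median was 6.03 (camera adjusted p = 6.97e-10; adjusted p = 0.294 with an estimated correlation). Besides RAB21, RAB16B and RAB16C, the members RAB16D (6.03, SE 0.460) and Emp1 (5.72, SE 0.456), which encodes a late embryogenesis abundant protein, were among them (both chosen after their values were seen). Both F1 root arrays lay above all 4 parental root arrays for 9 of 9 list genes.

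Genes for a lectin and for chitinases, enzymes that break down fungal cell walls, rose as well. Agglutinin went up by 6.43 (SE 0.417, adjusted p = 3.02e-05), from 64.3 ± 18.0 in C bao and 106 ± 40.6 in Jamaica to 8397 ± 1527 in F1 roots (n = 2 each). Cht9 increased by 6.15 (SE 0.443, adjusted p = 4.65e-05). Its signal was 19.2 ± 25.9 in C bao, 1405 ± 371 in Jamaica and 14908 ± 4915 in F1 roots (n = 2 each). Cht11 (4.22, SE 0.352) and Cht4 (3.69, SE 0.831) followed. In the list of chitinases and glucanases, 5 of 13 genes rose, 1 fell and 7 did not pass (6 and 1 adjusted over the list alone). The list median was 1.01 (camera adjusted p = 0.00389; adjusted p = 0.294 with an estimated correlation) and 0.65 without Jamaica root replicate 2.

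Jasmonate genes formed the remaining list with a rise in F1 roots. JAZ13, a repressor of jasmonate signalling that is itself induced by the hormone, rose by 4.37 (SE 0.249, adjusted p = 3.02e-05), from 215 ± 46.7 and 135 ± 57.3 to 3761 ± 9.69 (n = 2 each). TIFY11A (3.97, SE 0.485) and JAZ10 (2.63, SE 0.205), of the same family, rose too. Across the list 8 of 34 genes rose, 2 fell and 24 did not pass (11 and 3 adjusted over the list alone). The list median was 0.23 with the deposited scaling but −0.02 with median centring, and the mean was 0.71. The camera adjusted p was 0.00783 (adjusted p = 0.358 with an estimated correlation).

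Some genes for nitrogen uptake fell in F1 roots, as did those of nonsymbiotic haemoglobins, which scavenge nitric oxide. DUR3, a urea transporter, fell by 3.69 (SE 0.414, adjusted p = 0.000622), from 950 ± 157 and 224 ± 128 to 20.05 ± 5.44 (n = 2 each). The nitrate transporter gene NRT2.3 fell by 3.20 (SE 0.354, adjusted p = 0.000578), from 4717 ± 534 and 3071 ± 1029 to 397 ± 68.2 (n = 2 each). AMT1, an ammonium transporter gene, fell by 1.61 (SE 0.173), while the glutamine synthetase gene GLN1-3 rose by 3.61 (SE 0.581). NSHB2 fell by 3.47 (SE 0.220, adjusted p = 3.02e-05), from 2773 ± 484 in C bao and 15185 ± 1100 in Jamaica to 570 ± 38.4 in the hybrid (n = 2 each). NSHB1 dropped by 3.32 (SE 0.307), with smaller changes of −1.77 and −1.95 for its 2 other probe sets. COPT2, a copper transporter gene, decreased by 2.66 (SE 0.414), and PTH1-2 by 2.21 (SE 0.264).

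Of the 15 genes in the list of nitrogen uptake and assimilation, which does not hold DUR3, 1 rose (GLN1-3), 3 fell and 11 did not pass in F1 roots (1 and 7 adjusted over the list alone). The falls were NRT2.3, AMT1 and AMT2-1 (−1.02, chosen after its value was seen). The list median was −0.75 (camera adjusted p = 0.00195; adjusted p = 0.296 with an estimated correlation). Of 14 phosphate genes 0 rose, 2 fell and 12 did not pass (1 and 3 adjusted over the list alone). SPX2 (−1.72) and PHT1-2 (−1.17) were the falls. The phosphate median was −0.37 (camera adjusted p = 0.0132; 0.0544 with median centring; adjusted p = 0.358 with an estimated correlation). Photosynthesis genes, markers of greening, had a median of −0.68, and 0 of 11 rose, 3 fell and 8 did not pass (0 and 8 adjusted over the list alone). The camera adjusted p was 0.000119 (adjusted p = 0.331 with an estimated correlation), and without F1 root replicate 2 the median was −1.06. The falls were in the chlorophyll-binding protein genes RCABP89 (−1.33) and RCABP69 (−0.91) and in the plastocyanin gene PETE (−1.08). The mean log2 signal of this list was 8.39 and 8.90 on the F1 root arrays, 8.82 and 8.75 on those of Jamaica and 9.61 and 9.94 on those of C bao.

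Further stress genes rose without their list passing. Of 14 oxidative stress genes, 3 rose in F1 roots (CAT-A 1.42, APX8 1.09 and RBOHB 0.85), 0 fell and 11 did not pass (5 and 0 adjusted over the list alone; camera adjusted p = 0.0712). Of 43 genes of the heat shock list 3 rose, among them HSF01 (1.98) and CLPB1 (1.91), 3 fell and 37 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.25). The falls included ARD1 (−1.53), which a synonym brought into the list although it encodes a dioxygenase of methionine salvage, and HSP18.8 (−1.20, chosen after its value was seen). Of 22 phenylpropanoid genes 3 rose (ROMT-17 1.28, CAD6 1.14 and 4CL5 1.05), 0 fell and 19 did not pass (3 and 1 adjusted over the list alone). Of 6 WRKY genes 1 rose, WRKY71 at 2.35 (SE 0.188), and 5 did not pass (2 and 0 adjusted over the list alone). Of 22 iron genes 1 rose (IRT1 1.97), 2 fell (YSL12 −1.34 and YSL16 −1.31) and 19 did not pass (2 and 4 adjusted over the list alone; camera adjusted p = 0.0552). ACO1, whose product makes ethylene, rose by 4.32 (SE 0.680), and R1C-Prx, a 1-Cys peroxiredoxin gene, by 4.403 (SE 0.345).

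Growth and diterpenoid genes gave few calls in F1 roots. Of 52 auxin genes 2 rose (ARF15 1.54 and GH3-8 1.44), 1 fell (GH3.5 −0.87) and 49 did not pass. Of 35 cell wall genes 1 rose (EXLA2 1.51), 1 fell (EXPB9 −1.66) and 33 did not pass. NAC genes gave 1 rise (NAC068 1.38) and 1 fall (NAC071 −1.21) among 8. No gene of dividing cells (0 of 33), of the diterpenoid phytoalexins (0 of 17) or of the seed storage list fixed in advance (0 of 9) passed. Nor did any of 23 ribosomal, 15 endoplasmic reticulum chaperone, 6 glutathione transferase and 13 chlorophyll synthesis genes. Of 9 defence marker genes fixed in advance and found by name, each judged on its probe set of highest mean, 0 passed in F1 roots, where PBZ1 differed by −0.07 and AOS2 by −0.05. For the chitinase marker Cht2, whose judged probe set differed by 0.70, the 2 other probe sets passed upward in F1 roots (3.16 and 2.23) and leaves (1.91 and 1.64). Of these only the first in root had an F1 mean above both parental means.

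In all, 2174 probe sets differed between F1 roots and the mid-parent value, 1449 higher and 725 lower (66.65% higher), and 463 lay beyond both parents, 346 higher and 117 lower (74.73% higher). The split depended on scaling. With median centring it was 1033 higher and 2111 lower (32.86% higher), and 269 and 263 (50.56% higher) beyond both parents. The median change of all probe sets was 0.12 as deposited, −0.01 with quantile scaling and −0.13 with median centring. The F1 root arrays had median signals of 62.5 and 64.15, the others 50.1 to 56.8. Both F1 root arrays lay above all 4 parental root arrays for 18.94% of probe sets and below them for 11.09%. By chance 6.667% each way arise if all 6 root arrays are interchangeable, and fewer can arise where the parents differ.

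Leaving out 1 array moved the count of 2174 to 1250 (C bao root replicate 2), 1336 and 1420 (Jamaica root replicates 1 and 2), 539 and 638 (F1 root replicates 1 and 2), and 3375 and 3378 (F1 leaf replicates 1 and 2), and in the same order the 463 beyond both parents to 177, 200, 159, 87, 119, 731 and 737, with 231 without C bao root replicate 1. Of 48 named root genes 21 passed without any 1 array, PM1, RAB16B, RAB16C, Agglutinin, Cht9, Cht11, JAZ13, DUR3, NRT2.3, NSHB1 and NSHB2 among them, and 27 did not pass without 1 of the F1 root arrays, such as RAB21 (adjusted p = 0.0553 and 0.0625 without replicates 1 and 2), ACO1 (0.0722 and 0.0577), GLN1-3 (0.0921 and 0.0588), IRT1 (0.0592 and 0.0553), CLPB1 (0.0656 and 0.0727) and, without replicate 1, COPT2 (0.0797), Cht4 (1.98, 0.301), RCABP89 (−0.66, 0.371) and PETE (−0.66, 0.267).

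**Figure D2:**
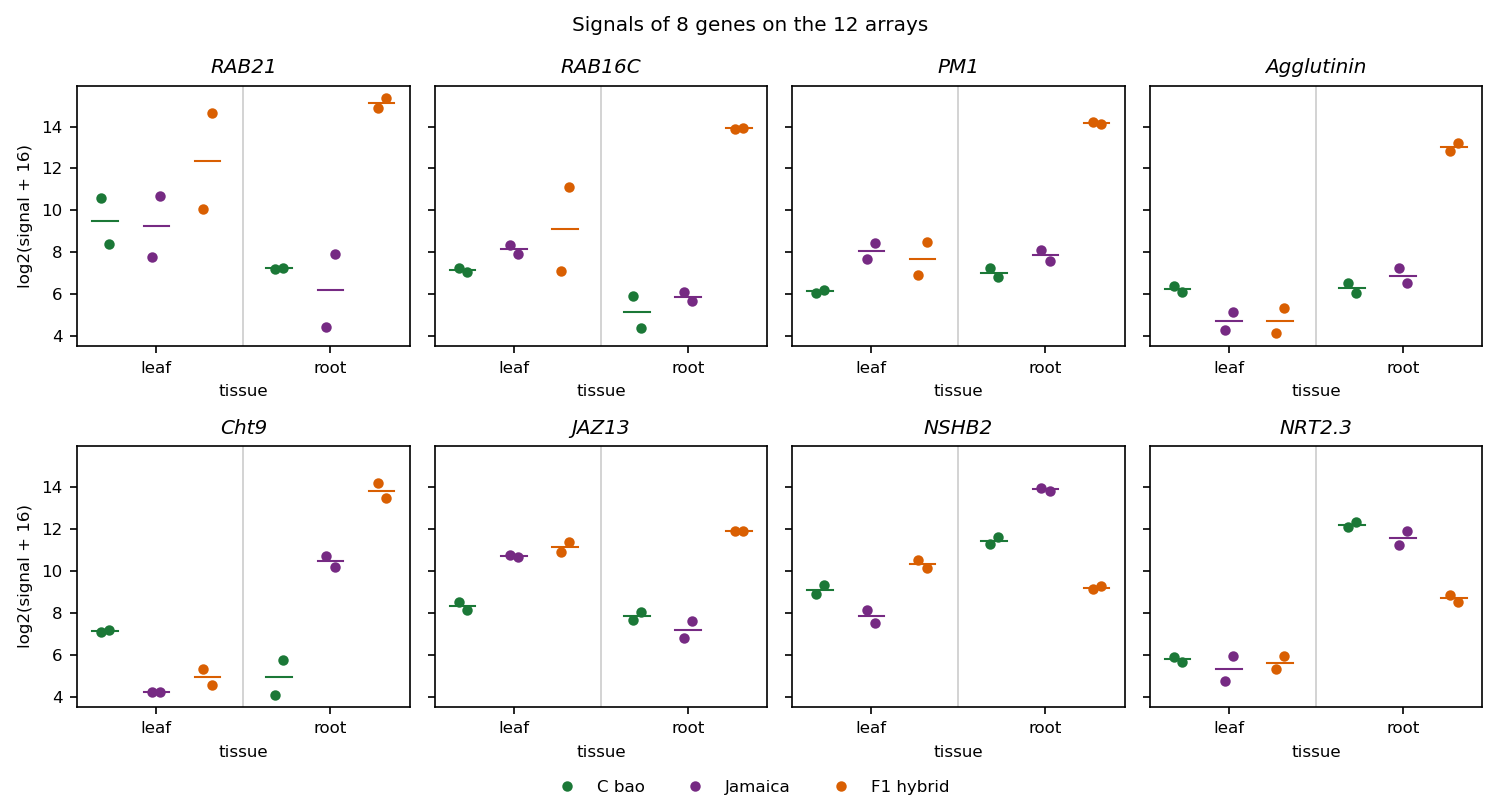
Log2(signal + 16) of 8 genes (y axis) in C bao (green), Jamaica (purple) and F1 hybrid (orange) leaf and root (x axis), with points for single arrays and lines for the mean of the 2 arrays of a group. RAB21, RAB16C, PM1, Agglutinin, Cht9 and JAZ13 were highest in F1 roots (8.42, 8.39, 6.73, 6.43, 6.15 and 4.37 above the mid-parent value), while NSHB2 and NRT2.3 were lower in F1 than in parental roots (−3.47 and −3.20 against the mid-parent value), with leaf signals that were as low or lower in some groups.

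The jasmonate repressor genes JAZ10 and JAZ13 passed in F1 leaves as in F1 roots, but TIFY11A of that family did not (1.73, adjusted p = 0.15). JAZ10 rose by 1.75 (SE 0.205, adjusted p = 0.00258), from 1389 ± 61.9 in C bao and 3029 ± 1112 in Jamaica to 6848 ± 792 in F1 leaves (n = 2 each). JAZ13 rose by 1.61 (SE 0.249) and LOX5, a lipoxygenase gene of the pathway that can feed jasmonate synthesis, by 0.97 (SE 0.171). HSF1, a heat shock factor gene, rose by 1.94 (SE 0.244, adjusted p = 0.00394), from 101 ± 12.9 and 202 ± 18.1 to 603 ± 152 (n = 2 each), and WRKY24 by 1.84 (SE 0.296, adjusted p = 0.0147). A class III peroxidase gene fell by 3.02 (SE 0.319, adjusted p = 0.0015), from 635 ± 166 in C bao and 10958 ± 5379 in Jamaica to 308 ± 96.5 in F1 leaves (n = 2 each).

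Across the leaf lists, 3 of 34 jasmonate genes rose, 0 fell and 31 did not pass (4 and 4 adjusted over the list alone; median 0.06; camera adjusted p = 0.843). Heat shock genes gave 1 rise and 1 fall (HSP81-1 −0.67) among 43, and chitinases and glucanases 0 rises and 1 fall (Rcb4 −1.58) among 13. NAC067 (0.94) was the sole rise among 8 NAC genes and WRKY24 among 6 WRKY genes. Phenylpropanoid genes gave 1 rise (4CL5 0.98) and 1 fall (CAD6 −1.25) among 22, and nitrogen genes 1 fall (AMT3-3 −1.56) among 15. For CAD6 the F1 leaf mean of 74.2 lay between the parents (689.9 in C bao, 49.1 in Jamaica). So did that of AMT3-3, at 140.1 (87.9 in C bao, 2235.7 in Jamaica). Of the 9 defence marker genes 0 passed: PBZ1 differed by −1.32 (adjusted p = 0.309), SGR, which acts in chlorophyll breakdown, by 1.16 (0.211) and NH1 by −0.80 (0.0802).

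Leaf lists passed camera with few or no single genes passing. The dehydration list had a median of 1.87 (0 of 9 genes passed, 1 adjusted over the list alone; camera adjusted p = 0.00177; adjusted p = 0.456 with an estimated correlation), and the median was 2.85 and 0.01 without F1 leaf replicates 1 and 2. Ribosomal protein genes had a median of −0.40 (0 of 23 passed, 10 fell adjusted over the list alone; adjusted p = 1.24e-10; 0.456 with an estimated correlation), and of −0.66 and −0.18 without F1 leaf replicates 1 and 2. Endoplasmic reticulum chaperones had a median of −0.35 with 1 fall, PDIL2-2 at −0.71, among 15 (6 adjusted over the list alone). Their adjusted p was 0.00225, 0.456 with an estimated correlation and 0.18 without F1 leaf replicate 2 (median −0.12, or −0.64 without replicate 1). Photosynthesis genes had a median of −0.45 (0 of 11 passed; adjusted p = 0.00236; 0.456 with an estimated correlation), which was −0.17 with quantile scaling (0.242) and −0.15 without F1 leaf replicate 1 (0.682), but −0.73 without replicate 2.

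In F1 leaves 522 probe sets differed from the mid-parent value, 422 higher and 100 lower. Of the 422, the F1 mean lay above both parental means for 249 (59%), and their median change of 1.76 was 0.97 against a mid-parent value on the linear scale. Beyond both parents limma called 1 probe set, with 1181 at unadjusted p below 0.05. It was LOC4347744, with a signal of 1553 ± 81.9 in F1 leaves, 277 ± 13.3 in C bao and 265 ± 72.6 in Jamaica (n = 2 each), a rise of 2.42 over C bao (SE 0.223, limma adjusted p = 0.0196 beyond both parents) and of 2.51 over Jamaica. It rose by 2.22 in F1 roots. Both F1 leaf arrays lay above all 4 parental leaf arrays for 6.15% of probe sets and below them for 7.13%. By chance 6.667% each way arise if all 6 leaf arrays are interchangeable. Fewer can arise where the parents differ, so this is not a strict baseline.

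The leaf count of 522 moved to 347 and 224 without C bao leaf replicates 1 and 2, 928 without Jamaica leaf replicate 2, 2231 and 1572 without F1 leaf replicates 1 and 2, and 319 and 322 without F1 root replicates 1 and 2, while the 1 probe set beyond both parents became 0 without any C bao leaf array or any C bao, Jamaica or F1 root array, 8 and 27 without Jamaica leaf replicates 1 and 2, and 223 and 8 without F1 leaf replicates 1 and 2. With the leaf arrays fitted alone the 522 were 42, and 0 of the 13 leaf genes named above for the mid-parent comparison passed (JAZ10 adjusted p = 0.0911, HSF1 0.106, peroxidase 0.0622), whereas 4 of the 13 (HSF1, JAZ10, Rcb4 and the peroxidase) passed without any 1 array and 9 did not, such as JAZ13 (0.0531), WRKY24 (0.0558) and NAC067 (0.0674) without C bao leaf replicate 2.

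**Figure D3:**
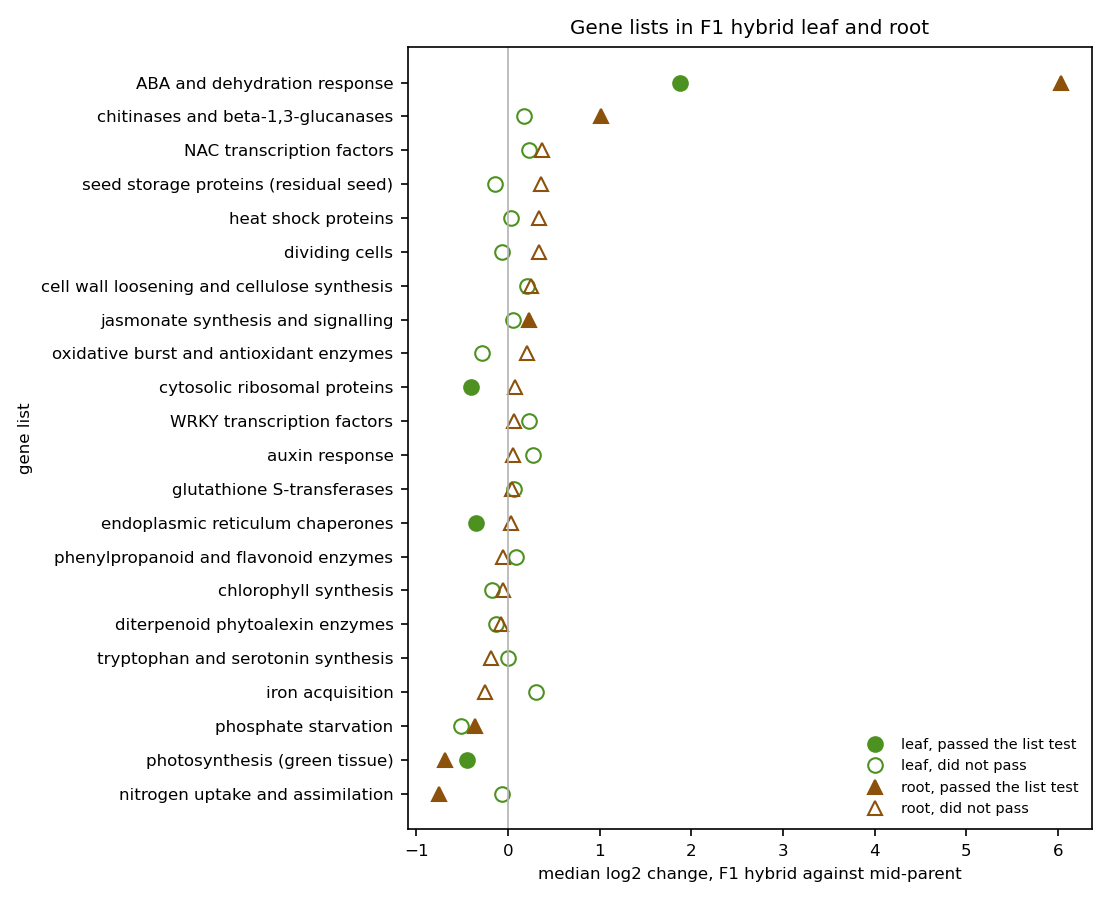
Median log2 change of F1 against the mid-parent value (x axis) for each gene list (y axis), circles for leaf and triangles for root, filled where the list passed camera. The dehydration list had the largest medians (6.03 in root, 1.87 in leaf), while the photosynthesis list was below 0 in both (−0.68 and −0.45), and the root jasmonate median of 0.23 turned to −0.02 with median centring.

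Of 422 probe sets higher in F1 leaves and 1449 higher in F1 roots, 246 were the same (14.23 expected were the tissues independent), and of the lower ones 8 (1.687 expected). In opposite directions, 16 were lower in leaf and higher in root (3.372 expected) and 9 higher in leaf and lower in root (7.119 expected). Because leaf and root calls used the same spread estimate per probe set, they were not independent. All expected numbers of this paragraph may therefore be too low. A gene that differs between the parents in both tissues can exceed the mean of the log2 values in both while F1 lies between the parents, as for FDRMADS8 (3.08 in leaf and 2.28 in root). Among the 246, F1 lay between the parental means in both tissues for 107 and above both parents in both tissues for 116. Of the rises with F1 above both parental means, 249 in leaf and 1257 in root, 116 were shared (7.283 expected), a split made after the values were seen. Across the 2417 probe sets called in either tissue the changes correlated at r = 0.34, and across all probe sets at r = 0.16.

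The haemoglobin genes changed differently in leaf and root. NSHB2 differed by 5.34 between leaf and root (leaf change minus root change, SE 0.311, adjusted p = 0.000167) and NSHB1 by 5.19 (SE 0.435, adjusted p = 0.000963), where the leaf estimates alone were 1.88 and 1.87. The 2 other NSHB1 probe sets changed less. They gave 0.45 and 0.74 in leaf (limma adjusted p = 0.718 and 0.477) and −1.77 and −1.95 in root. Signal shared between NSHB1 and NSHB2 was not excluded, so they may not be independent results. LAC24, a laccase gene, differed by 4.62 (SE 0.805) with a leaf rise of 4.09 (SE 0.569), and CPDK2, a calcium-dependent protein kinase gene, by 4.05 (SE 0.573). For CPDK2 the leaf change was 0.82 (limma adjusted p = 0.444). Its root signals were 109 ± 38.4 in C bao, 6488 ± 4414 in Jamaica and 74.3 ± 22.2 in F1 (n = 2 each). F1 roots were thus near C bao, and the difference rested on a high and variable Jamaica root signal. On the side of larger root changes were Agglutinin (−7.18, SE 0.590), RAB16C (−6.92, SE 1.19), Cht9 (−6.88, SE 0.627) and PM1 (−6.14, SE 0.566). RAB21 (−5.45, adjusted p = 0.217) and RAB16B (−5.18, adjusted p = 0.173) did not pass.

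The dehydration list had a median leaf minus root difference of −4.71, with 0 of 9 genes higher in leaf, 4 in root and 5 not passing (camera adjusted p = 1.61e-06; adjusted p = 0.383 with an estimated correlation). Chitinases and glucanases (−0.84, adjusted p = 0.000716; 0.175 estimated), ribosomal proteins (−0.49, 1.61e-06; 0.616), oxidative stress (−0.48, 0.00132; 0.142) and jasmonate (−0.35, 0.0152; 0.616) also passed, and iron genes in the other direction (0.67, 0.00651; 0.142). In all 477 probe sets passed, 185 higher and 292 lower (38.78% higher), which median centring turned into 573 and 219 (72.35% higher). The median of all probe sets was −0.13 as deposited, 0.00 with quantile scaling and 0.17 with median centring.

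The count of 477 moved to 269 and 241 without C bao leaf replicates 1 and 2, 260 and 205 without C bao root replicates 1 and 2, 247 and 225 without Jamaica root replicates 1 and 2, 2005 and 1414 without F1 leaf replicates 1 and 2, and 68 and 104 without F1 root replicates 1 and 2. Without F1 root replicates 1 and 2, CPDK2 (adjusted p = 0.0621 and 0.0739), LAC24 (0.141 and 0.144) and RAB16C (0.145 and 0.139) did not pass, while the other 5 named genes passed without any 1 array.

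Single genes differed widely in signal between the parents. FDRMADS8, a MADS-box gene, had a signal of 4389 ± 420 in C bao and 10.9 ± 7.14 in Jamaica leaves, and 5361 ± 631 and 4.70 ± 4.10 in roots (n = 2 each). The differences were 7.38 in leaf (SE 0.265, adjusted p = 1.08e-07) and 8.03 in root (SE 0.265, adjusted p = 8.88e-08), and since the Jamaica signals lay below the filter level of 32.2 their size depends on processing (5.89 to 8.66 and 6.30 to 10.09 over the alternatives). OsC3H2 was higher in C bao leaves (5.47, SE 0.269) and OsPRDA1 in C bao roots (5.24, SE 0.472). HSP18.0 was lower in C bao leaves (−5.66, SE 0.317), as was METK3, which encodes S-adenosylmethionine synthetase (−5.18, SE 0.339). The autophagy gene APG8D (−5.57, SE 0.318) and the glutaredoxin gene GRXS1 (−4.47, SE 0.201) were lower in C bao roots. Probe sets of 1 gene did not always go together: Cht2 was higher in C bao by 1 probe set (6.35 in leaf, 4.81 in root) and lower by another (−5.19 and −6.36). The other OsPRDA1 probe set was lower in C bao (−1.96 in leaf, −0.71 in root, the latter not passing), and 1 of the 2 others of HSP18.0 (0.05 in leaf) and the other of OsC3H2 (1.52 in leaf, 0.09 in root) showed little or less of the difference.

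Growth genes were higher in C bao than in Jamaica leaves. Of 33 dividing-cell genes 9 were higher, 0 lower and 24 did not pass (18 and 0 adjusted over the list alone), with a median of 1.56 (camera adjusted p = 0.000216; adjusted p = 0.693 with an estimated correlation). Of 35 cell wall genes 11 were higher, 0 lower and 24 did not pass (median 1.49; adjusted p = 0.000216; 0.693 with an estimated correlation). Of 52 auxin genes 14 were higher and 1 lower (median 0.51; adjusted p = 0.00819; 0.693 estimated). The photosynthesis list passed camera as lower in C bao leaves (adjusted p = 0.00343), with 0 higher, 2 lower and 9 not passing of 11 and a median of −0.63. It did not pass with an estimated correlation (0.693) or with quantile scaling (0.141). The heat shock list also passed camera as lower (adjusted p = 0.0353), but not with an estimated correlation (0.693). Of its 43 genes 1 was higher, 5 were lower and 37 did not pass (median −0.35).

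In roots, photosynthesis genes were higher in C bao than in Jamaica (5 higher, 1 lower and 5 not passing of 11, median 1.26; camera adjusted p = 2.03e-05; 0.493 with an estimated correlation). Chlorophyll synthesis (median 0.57; adjusted p = 0.0209; 0.565 estimated) and nitrogen genes (median 0.43; adjusted p = 0.00745; 0.493 estimated) had 1 higher gene each. Diterpenoid phytoalexin genes were lower in C bao roots (0 higher, 7 lower and 10 not passing of 17, median −2.09; adjusted p = 2.5e-05; 0.493 estimated), as were genes of tryptophan-derived defence compounds (0 higher, 3 lower and 3 not passing of 6, median −1.36; adjusted p = 0.00478; 0.493 estimated).

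Between the parents 5095 probe sets differed in leaf (3207 higher in C bao, 1888 lower) and 2019 in root (1026 and 993). Probe sets higher in C bao in both tissues numbered 515 (76.57 expected) and those higher in Jamaica 378 (43.63 expected). The expected numbers assume independent calls, although both tissues shared 1 spread estimate per probe set. Where both tissues gave a call (966 probe sets) the differences correlated at r = 0.89, and over all probe sets at r = 0.29. The leaf count of 5095 became 1537 and 2150 without C bao leaf replicates 1 and 2, 2064 without Jamaica leaf replicate 1, and 8103 and 8092 without F1 leaf replicates 1 and 2. The root count of 2019 became 1166 and 1048 without C bao root replicates 1 and 2, and 996 and 1156 without Jamaica root replicates 1 and 2.

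On the mean of the 2 F1 leaf arrays, the hybrid lay nearer to C bao than to Jamaica across the 5095 probe sets that separated the parents in leaf. On a scale from 0 (Jamaica) to 1 (C bao) the median position was 0.669 (quartiles 0.474 and 0.856), and 72.42% lay nearer to C bao. Split after the values were seen, F1 leaves lay at 0.685 of the way from the lower to the higher parent where C bao was higher (3207) and at 0.377 where Jamaica was higher (1888), and on the linear scale at 0.488 and 0.253. F1 leaves differed from Jamaica alone at 1582, from C bao alone at 299, from both at 64 and from neither at 3150. In roots the median position was 0.533 (quartiles 0.222 and 0.851), with 682 different from Jamaica alone, 580 from C bao alone, 160 from both and 597 from neither. F1 roots lay nearer to the higher parent on the log2 scale whichever it was (0.735 for C bao, 0.635 for Jamaica), with 0.523 and 0.427 on the linear scale. The 2 F1 leaf arrays stood apart in how near they lay to C bao. On the main axis of variation among the leaf arrays (53.4% of the variance), C bao lay at −112.7 and −93.4 and Jamaica at 154 and 100.6. F1 leaf replicate 1 lay at −83.4, beside C bao, and replicate 2 at 34.9, between the parents. Replicate 1 minus replicate 2 correlated across probe sets at r = 0.447 with C bao minus Jamaica in leaf. For the dividing-cell genes F1 leaf replicate 1 (9.86) stood beside C bao and replicate 2 (7.72) beside Jamaica. The count of 3150 became 605 and 973 without C bao leaf replicates 1 and 2 and 1042 without Jamaica leaf replicate 1, and the root count of 597 became 282 and 269 without C bao root replicates 1 and 2, 241 and 270 without Jamaica root replicates 1 and 2, and 997 and 912 without F1 root replicates 1 and 2.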

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

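The RNA degradation, seed storage, drying and growing-tissue tests of the parents, and the leaf form of the second-probe-set test, were chosen only after the result was seen.

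The 2 F1 leaf arrays differed more than any other replicate pair. A parental plant in place of a hybrid was excluded, as the arrays lay at 0.759 and 0.689 between Jamaica (0) and C bao (1) over 348 probe sets with large parental differences in both tissues, with F1 roots at 0.781 and 0.801, and near the higher parent whether that was C bao (0.826 and 0.806) or Jamaica (0.167 and 0.192), where a parental plant would lie near 1 parent in both. Growing tissue in unequal share could explain the difference: 31 of 33 dividing-cell genes were higher on replicate 1, with a median of 1.82, above the highest of 10000 random lists (0.79). The random genes were drawn singly, whereas the dividing-cell genes vary together (estimated correlation 0.579). The random lists therefore cannot tell growing tissue from RNA quality or stress. RNA degradation stayed open, since the 3' to 5' ratio on replicate 2 was above all 5 other leaf arrays for 2 of 4 control transcripts. A true difference between 2 plants in growth or in stress stayed open as untested, and the dehydration list was 1.96 higher on replicate 2, for 9 of 9 genes.

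Dehydration genes rose in F1 roots far above both parents. Probes that match 1 parent better were excluded, since F1 signals would then lie between the parents and 9 of 9 genes were above all 4 parental root arrays. Embryo or seed tissue left on F1 roots stayed open. The 3 embryo markers had a median of 0.35 and none passed, the result set down beforehand for excluding it. However, GLB had a high baseline in C bao roots (2987) and VP1 lay below the filter level in each root group (at most 11.5). That test therefore rested on 1 gene, TIP3-2, with a low baseline (35.5 in C bao, 79.6 in Jamaica, 92.8 in F1). Its change of 0.646 (SE 0.464) was small beside those of the dehydration genes, yet both F1 root arrays lay above all 4 parental root arrays. In another set of 9 seed genes, 6 of them above the filter and so tested, the median was 0.47 (−0.90 to 3.73), the tested storage protein genes did not pass and TIP3, absent from the seed list fixed in advance, did, and joining both marker sets into 1 answer was decided after their values were seen. Drying of F1 roots between harvest and freezing stayed open, as the list median of 1.87 in F1 leaves, against a handling of roots alone, was 0.007 without replicate 2, and stress caused by the hybrid genotype itself, which the series title names, stayed open as untested.

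Many probe sets differed between the parents in both tissues, with 5095 in leaf and 2019 in root. Sequence differences under the probes could have contributed in root. Another probe set of the gene moved the same way there for 72 of 153 (47.06%, 95% CI 38.95 to 55.28). For those beyond both parents in F1 roots it did for 29 of 38 (76.32%, 59.76 to 88.56), 29.3 points apart. The 38 had to pass against both parents, a stricter choice, so the gap alone does not settle this. A mismatch would act in both tissues. Yet the shares were similar for leaf differences called in both tissues (57.3%, 46.37 to 67.74) and for those not called in root (63.41%, 57.06 to 69.44). In leaf the gap of 15.6 points (198 of 326, 60.74%) left this open. A larger share of growing tissue in C bao leaves could explain part of the leaf count, as dividing-cell genes had a median of 1.56 in leaf and −0.20 in root. Regulatory differences between the cultivars stayed open as untested.

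The leaf and root effects of the hybrid differed at 477 probe sets, and among the named genes the leaf minus root differences were −7.18 (Agglutinin), −6.92 (RAB16C), −6.88 (Cht9), −6.14 (PM1), −4.66 (Cht11), −3.90 (the leaf peroxidase), −3.90 (R1C-Prx), −2.76 (JAZ13), −2.39 (CAD6), −1.70 (APX8), −1.56 (WRKY71), −1.47 (ARF15), −1.42 (CAT-A), 1.32 (YSL12), 1.61 (AMT1), 2.15 (PTH1-2), 2.37 (EXPB9), 3.27 (NRT2.3), 4.05 (CPDK2), 4.62 (LAC24), 5.19 (NSHB1) and 5.34 (NSHB2).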

How the results depend on the processing

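Leaving out both F1 leaf arrays and the dividing-cell covariate were tests chosen only after the result was seen. For the 95 called gene results, 1156 of 1301 comparisons with alternatives other than leaving out an array showed no change, 132 lost the call and 13 moved in size (all with a linear mid-parent value, which has no test); leaving out an array kept 943 of 1140 calls and lost 197. The 18 results not called gained a call in 2 of 252 and 3 of 216 comparisons. The 10 called lists kept their call in 34 of 50 comparisons and in 117 of 120 without 1 array, and the 34 others gained one in 10 of 170 and 22 of 408. Each of the 12 arrays was left out in turn, also for results within 1 tissue. Arrays of the other tissue do not enter the group means of such a result, so the shares kept overstate how well calls hold. Without F1 leaf replicate 2 the test of the leaf dehydration list turned direction, with a median of 0.007 (adjusted p = 0.971; 2.85 without replicate 1), as did dividing cells in leaf, with 0.81 (3.67e-07; −1.01 without replicate 1); leaf lists passing without 1 array numbered 4 to 9; with an estimated correlation 0 lists passed in leaf and 0 in root, and fry gave 0 in leaf. Counts are given as F1 against mid-parent, beyond both parents, C bao against Jamaica, and different from neither parent. Each tissue alone gave 42, 0, 1159 and 728 in leaf and 5099, 1456, 4159 and 905 in root. Array weights gave 131, 0 and 5230 (neither) in leaf and 4997, 1055 and 3378 (parents) in root. A threshold of 0.01 gave 178, 0, 1815 and 1103 in leaf, 942, 191, 1079 and 381 in root and 120 for leaf minus root. Beyond both parents, leaf counts were 13 with quantile scaling, 8 with median centring, 9 with a pseudocount of 64, 0 without trend and 8 with robust moderation, and root counts 282 without trend. Leaf minus root counts were 792 with median centring, 757 with a pseudocount of 64 and 253 without trend. The replicate block gave 299 for F1 leaves, 0 and 290 beyond both parents and 236 for leaf minus root; replicate numbers do not pair the samples, and deviations of paired numbers correlated at −0.168, 0.064 and −0.125 in leaf and −0.049, 0.02 and −0.009 in root. Added after the data had been seen, root counts without both F1 leaf arrays were 3411 and 749 (beyond), and leaf counts with the dividing-cell covariate 1241, 0, 1104 and 163 (neither). Leaving out 1 array gave 224 to 2231 for F1 leaves, 0 to 223 beyond both parents in leaf, 539 to 3378 for F1 roots, 87 to 737 beyond both parents in root, 1537 to 8103 for leaf parents, 996 to 2753 for root parents, 68 to 2005 for leaf minus root, and 605 to 4349 and 241 to 997 for neither parent in leaf and root. The cause was not tested for any of these changes. Root means do not use the F1 leaf arrays, so leaving those out could change root counts only through the shared spread estimate and the filter. The correlation of the F1 effects was 0.16 over all probe sets and 0.335 over those called. The root dehydration median stayed between 5.86 and 6.20. A lone array left in a group is assumed to vary like the other groups. Signal over background limits the size of falls to, and differences from, low values, since DUR3 at 20.05 in F1 roots and FDRMADS8 at 10.9 in Jamaica leaves are near the added 16.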

Other observations

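All genes and both families of the first 2 paragraphs, and their tests, were chosen only after the result was seen, so the family counts describe these genes and do not test them. Several cold-response transcription factor genes rose in the hybrid. DREB1B rose by 3.01 in leaf (SE 0.303, adjusted p = 0.00126), from 312 ± 29.8 in C bao and 628 ± 279 in Jamaica to 3602 ± 603, and by 4.76 in root (SE 0.303, adjusted p = 3.02e-05), from 107 ± 34.2 and 159 ± 55.4 to 3899 ± 834 (n = 2 each). CBF3 rose by 1.83 in leaf (SE 0.301; adjusted p = 0.0523 without C bao leaf replicate 1 and 0.106 with the leaf arrays alone) and by 4.91 in root (SE 0.301), and DREB1G by 2.07 (not passing without 1 of 9 arrays, with adjusted p = 0.103 without C bao leaf replicate 1, and 0.0911 with the leaf arrays alone) and 2.995. DREB1E rose in root by 3.53 (SE 0.612) but not without F1 root replicate 1 (adjusted p = 0.0656) or 2 (0.121). Of 5 genes of this family 3 rose in leaf and 4 in root, 0 fell, and 2 and 1 did not pass (4 rises and 1 fall in leaf and 4 and 0 in root adjusted over the family alone). The family medians were 2.07 and 3.53.

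Genes for calmodulin-like proteins, which sense calcium, rose in part. CML15 rose by 2.95 in leaf (SE 0.343, adjusted p = 0.00248; 0.0869 with the leaf arrays alone) and 3.70 in root (SE 0.343, adjusted p = 0.000204), and CML31 by 2.29 (SE 0.338; 0.147 with the leaf arrays alone) and 1.87 (SE 0.338; adjusted p = 0.121 and 0.0972 without F1 root replicates 1 and 2). Of 23 genes 6 rose in leaf and 5 in root, 0 fell, and 17 and 18 did not pass (7 rises and 1 fall in leaf and 6 and 0 in root adjusted over the family alone). The median was 0.23 in leaf, and in root 0.17 as deposited, −0.01 with quantile scaling and −0.08 with median centring. SWEET12, a sugar transporter gene, rose by 5.02 in root (SE 0.540, adjusted p = 0.000501) and PDC1, the pyruvate decarboxylase gene of fermentation, fell by 4.94 (SE 0.657, adjusted p = 0.00168), where the Jamaica roots spread widely (8048 ± 8523, n = 2).

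In leaf, the metallothionein gene MT1B (2.87) also rose, chosen after its value was seen. NH1 passed without Jamaica leaf replicate 2 (−0.94, adjusted p = 0.0175), as did SGR (1.51, adjusted p = 0.0245), and CYP71P1 passed without F1 leaf replicate 1 (0.98, adjusted p = 0.0368).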
